A study of Mus musculus with 8 samples.

How the data were processed

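The series holds 8 libraries of muscle stem cells sorted from the skeletal muscle of C57Bl/6 mice, 4 from wild-type animals and 4 from Cox10-/- animals. Per the labels, a floxed Cox10 allele was combined with a tamoxifen-dependent Pax7-Cre driver, animals received 1 intraperitoneal dose of tamoxifen at 200 mg/kg, and cells were collected 2 days later. Cells were sorted as CD34 positive and negative for CD31, CD45, Sca1 and the dead-cell dye DAPI. Libraries were made from total RNA with a stranded low-input kit, per the labels' protocols. Each sample is labelled as a separate replicate, but no label states that each came from its own animal. The p-values of single genes therefore measure the spread between these samples.

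The submitters' processing notes name Trim Galore, HISAT2, featureCounts and DESeq2 and the mouse build mm9. Versions, the counting of strand and the treatment of reads with several matches are not given in the sources used here. The file is 1 table of the whole series, with gene symbols and 1 column per sample. The values deposited by the authors are log2 CPM, reads of a gene scaled to the reads of the library, as tested on the file. On the linear scale the columns sum to between 994342 and 995129 CPM. Values were rounded to 2 decimals, every CPM of 1 or less stands at 0, and the smallest mean of a gene over the 8 libraries is 0.5. A value of 0 therefore means a CPM of 1 or less, and not an absence of reads. The table has 17847 genes, and a further 1054 rows hold no gene. A total of 23 symbols had been turned into dates, and 2 of these stood on 2 rows. A column with the authors' mean over all samples was not used.

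The low values of each column were whole multiples of the worth of 1 read. Up to 20 reads, 100% of the low values of each library lay within 0.1 of a whole number of reads. The steps gave 1693349 to 4650051 reads counted in genes per library, and these recovered reads were used for depth, for the reads of Cox10, for simulated data and for 1 alternative test. No pair of libraries of a genotype agreed within sampling noise: chi-square per degree of freedom over recovered reads lay between 2.85 and 8.75. In both genotypes replicates 1 and 2, and replicates 3 and 4, were closest to each other (2.85 to 3.31, against 5.32 to 8.75 for the other 8 pairs). Whether these share an animal, a day or a preparation is not in the labels. All 8 libraries were kept as separate samples, since none agreed within sampling noise, but this does not show that they are independent, and if they are not, n = 4 is too high. Means of replicates 1 and 2 and of 3 and 4, as 2 samples per genotype, were therefore tested as well, after the data were seen.

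Cox10-/- was compared with wild-type by limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with no added pseudocount. The fit used genotype alone, a variance prior with a trend on mean expression, and Benjamini-Hochberg adjustment with a threshold of 0.05. Because of the floor at 0, the planned filter of a log2 CPM of 0 or more in at least 4 of the 8 libraries removed no gene as written. It was applied as a value above 0 in at least 4 libraries, which left 17801 genes and removed 46. The fit without a filter was run as an alternative. For genes with libraries at 0, a log2 fold change is a difference from the floor. It understates the change where those libraries belong to the lower genotype, and can overstate it where they belong to the higher one. Errors of log2 fold changes are standard errors of the fit, and ± SD is over 4 libraries.

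A set of 44 gene lists (pathways, complexes and markers of cells that the sort should exclude or that fibres contain) was fixed before the data were examined, as were the tests and a first set of other settings. Of 1097 list entries, 1041 were measured. Lists with at least 5 measured members, 43 in all, were tested by camera with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. With a preset correlation, camera sets a list against the spread over genes. Its p-values therefore do not measure the spread of a list between libraries. An estimated correlation, fry's directional test and fry's mixed test were alternatives. None of the 14 calls of the preset test held with an estimated correlation. Named genes were chosen by a fixed rule: Cox10, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between genotypes (predicted gene models left out), up to 4 members of each list with the smallest p, and Pax7, Myf5, Myod1, Myog, Xist and Ddx3y. Ddx3y was not analysed here. Not every gene that the rule selects is described. Where other genes were named, the text says that they were chosen after their values were seen.

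The same functions were tested on simulated data. Libraries were drawn for 17790 genes with the measured means and depths, with 200 genes changed. Their spreads came from the moderated variances of the fit, less sampling noise. The fit called 10.4% of genes changed by a log2 of 0.5, 53.7% of those changed by 1 and 90.9% of those changed by 2, and 8.85% of its 113 calls were false, above the nominal 5%. In the data 2863 genes were called. With fewer changed genes the adjusted threshold is stricter, so the simulated shares may understate how many such changes the fit called in the data. In 5 simulations with no change, at most 1 gene was called. Camera found 10 of 10 lists shifted by 0.5 and called 0 of 40 unshifted ones. Each list held 30 of the better expressed genes, and every member of a shifted list moved by 0.5. Many lists called in the data had smaller medians, such as 0.12 for lysosomal and -0.195 for cytosolic ribosomal transcripts. How often lists with such shifts are found was not simulated. Simulated genes were drawn independently, so this does not test the preset correlation.

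That first set held other filters, pseudocounts of 1 and 5, median centring, quantile normalization, library weights, other variance priors, a replicate block, each library left out in turn, removal of sex-linked transcripts and a threshold of 0.1. After the data were seen, fits with a second term for replicates 1 and 2 against 3 and 4, for a split of the libraries by mitochondrial transcripts or for depth were added. A fit without the 2 shallowest libraries, voom on the recovered reads, and a correction for transcript length and GC content, with and without the block, were added as well. Transcript lengths, GC content and shared 50-mers came from the longest transcript of each symbol in GENCODE M21, which matched 17560 of the 17801 tested symbols (98.6%). Gene order came from the RefSeq table of GRCm38.p6. Both belong to another build than the files, so no coordinates are given.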

Results

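RNA was measured in cells sorted as muscle stem cells, the Pax7-expressing cells that repair skeletal muscle. There were 4 wild-type and 4 Cox10-/- libraries, each set numbered as replicates 1 to 4. Reads counted in genes numbered 3548568, 2148645, 4650051 and 4024995 in wild-type replicates 1 to 4, and 4313903, 4348650, 3111035 and 1693349 in Cox10-/- replicates 1 to 4. Pearson correlations between libraries, across genes, were 0.958 to 0.981 within a genotype and 0.933 to 0.953 between genotypes. The first principal component held 39.7% of the variance and separated the genotypes.

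The comparison asks which transcripts differ in these cells 2 days after tamoxifen was given to delete Cox10, which encodes an enzyme of haem A synthesis needed by respiratory complex IV. In Cox10-/- cells, lists of transcripts of stem cell identity and Notch signalling, which share members, were lower by camera with a preset correlation. So were those of cholesterol synthesis, ribosome biogenesis, complex I and ATP synthase. Lists of mitotic transcripts, hypoxia-inducible factor targets, lysosomal transcripts, immediate-early genes and endothelial markers were higher by the same test. None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.229. The median of the immediate-early list was -0.12 in replicates 1 and 2. Pax7 fell by 1.29 ± 0.11 (log2, SE, n = 4 per genotype), and Trim63, a ubiquitin ligase of muscle protein breakdown, rose the most. Of 17801 genes tested with limma, 1349 rose and 1514 fell (2863 in all, 16.1%), and 561 and 535 of these changed by a log2 fold of 1 or more. All 4 libraries of one genotype lay above all 4 of the other in 90.2% of the changed genes and in 21.1% of all genes, where chance gives 2.86%. The count was 1902 without wild-type replicate 1 and 1840 without Cox10-/- replicate 3. Replicates 1 and 2, and replicates 3 and 4, resembled each other most in both genotypes. With their means as 2 samples per genotype, 858 genes changed (445 higher, 413 lower), and 13 of 14 list calls were kept. The means leave each log2 fold change as it was, and this list test rests on the spread over genes. The kept list calls therefore say little about whether the libraries are independent. Rises made up 47.1% of the changes as deposited and 58.4% after median centring.

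**Figure D1:**
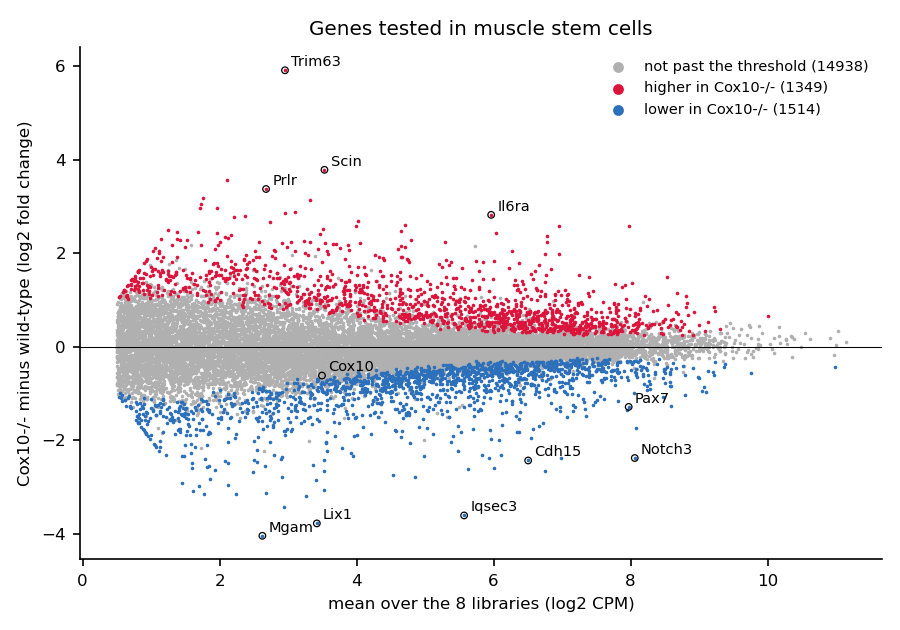
Each point is 1 of the 17801 genes, with its mean over the 8 libraries (log2 CPM) on the x axis and the log2 fold change of Cox10-/- against wild-type on the y axis. Genes past an adjusted p of 0.05 are coloured, 1349 higher and 1514 lower, and 11 genes are named.

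Cox10 itself was lower by an amount that did not pass the test. Its log2 fold change was -0.62 ± 0.34 (SE, n = 4 per genotype; limma adjusted p = 0.246; exact two-sided permutation p = 0.2 over 70 assignments, of which 0.0286 is the smallest possible p). The 95% interval, from the moderated standard error of the fit and its residual degrees of freedom, was -1.46 to 0.22. The geometric mean was 65.2% of wild-type. Wild-type replicates 1 to 4 held 56, 23, 81 and 52 Cox10 reads, and Cox10-/- replicates 1 to 4 held 49, 56, 35 and 7. The difference was -0.10 in replicates 1 and 2 and -1.13 in replicates 3 and 4, and -0.24 without Cox10-/- replicate 4. The labels do not name the floxed exon, and reads from the remaining exons count towards these values.

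Among the 10 largest rises of the genes chosen by rule, Trim63 was listed at 0 in all 4 wild-type libraries. It averaged 5.91 ± 0.26 log2 CPM (SD, n = 4) in Cox10-/-, at least 60.0-fold above the CPM of 1 at the floor. Scin, which encodes an actin-severing protein, rose by 3.78 ± 0.34 (SE), Aspg by 3.56 ± 0.38 and the prolactin receptor Prlr by 3.37 ± 0.40. The interleukin 6 receptor Il6ra rose by 2.82 ± 0.15 and Lyve1, a hyaluronan receptor of lymphatic endothelium, by 2.77 ± 0.39. St6galnac5 (3.13), Arhgef37 (2.88), Ctla2a (2.86) and She (2.80) completed the 10. Among the 10 largest falls, Mgam, a maltase, fell by 4.04 ± 0.34, Lix1 by 3.78 ± 0.35 and Iqsec3 by 3.61 ± 0.26. The carbonic anhydrase Car12 fell by 3.20 ± 0.48 and the ephrin receptor Ephb1 by 3.06 ± 0.24. Ntn5 (-3.44), Slc24a2 (-3.14), Ksr2 (-3.13), Pof1b (-2.95) and Nwd1 (-2.86) were the others. These 20 genes kept their call in all 8 fits that left out 1 library. For those with libraries at the floor of 0, all in the lower genotype, the values understate the fold. All 20 also kept their call in the test of 2 means per genotype.

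Genes of muscle stem cell quiescence and identity were lower. Of 40 measured, 16 fell, 1 rose and 23 did not pass (17 and 3 adjusted over the list alone), with camera adjusted p = 1.4e-04 and adjusted p = 0.229 with an estimated correlation. The cadherin gene Cdh15 fell by 2.43 ± 0.16, Notch3 by 2.38 ± 0.18, and Rapsn, which clusters acetylcholine receptors, by 1.80 ± 0.17. Pax7 went from 8.62 ± 0.15 to 7.33 ± 0.18 log2 CPM (SD, n = 4), and Myf5 fell by 0.95 ± 0.13. The member that rose, named after its values were seen, was Rgs2 (0.30 ± 0.10). Of 14 Notch pathway genes, 5 fell (Notch3, Heyl by 1.17 ± 0.12, Dll1 by 1.08 ± 0.17, Hey1 by 0.79 ± 0.11 and Notch1 by 0.61 ± 0.15) and 1 rose (Nrarp by 0.96 ± 0.30), with 6 and 1 adjusted over the list alone. Of those that fell, all but Dll1 are also members of the stem cell list, so the calls of these lists are not independent. Camera gave an adjusted p of 0.0246 for the Notch list, 0.351 as adjusted p with an estimated correlation, 0.0567 after median centring and 0.0501 after a correction for transcript length and GC content. Notch1 and Nrarp were named after their values were seen, and the calls of Nrarp and Rgs2 were lost in 8 and 7 of the 8 fits without 1 library (adjusted p up to 0.111 for each, without Cox10-/- replicate 2 and Cox10-/- replicate 3). The list of myogenic activation did not pass (camera adjusted p = 0.513): the determination factor Myod1 (-1.03), Megf10 (-0.77), Mest (-0.70) and Ncam1 (-0.45) fell, and the activin-binding Fst rose by 2.60 ± 0.52, with 4 falls and 1 rise of 16, as when adjusted over the list alone. Of 25 differentiation genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0819, and 0.0136, 0.0268 and 0.0162 without wild-type replicate 2, Cox10-/- replicate 3 and Cox10-/- replicate 4), among them the acetylcholine receptor subunit Chrna1 (-2.24), Jsrp1 (-1.38), the fusion factor Tmem8c (-2.48) and Myog (-1.51 ± 0.42). The call of Myog was lost in 5 of the 8 fits without 1 library, at an adjusted p of up to 0.077 without Cox10-/- replicate 2. The differentiation list also passed after median centring (0.0312), with a term for replicates 1 and 2 against 3 and 4 (0.0497), without the 2 shallowest libraries (0.0012) and with 2 means per genotype (0.0282). In the last of these the calls of Rgs2, Notch1, Nrarp, Mest, Ncam1 and Myog were lost. Endothelial markers were higher in the same libraries, with a median of 1.10.

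**Figure D2:**
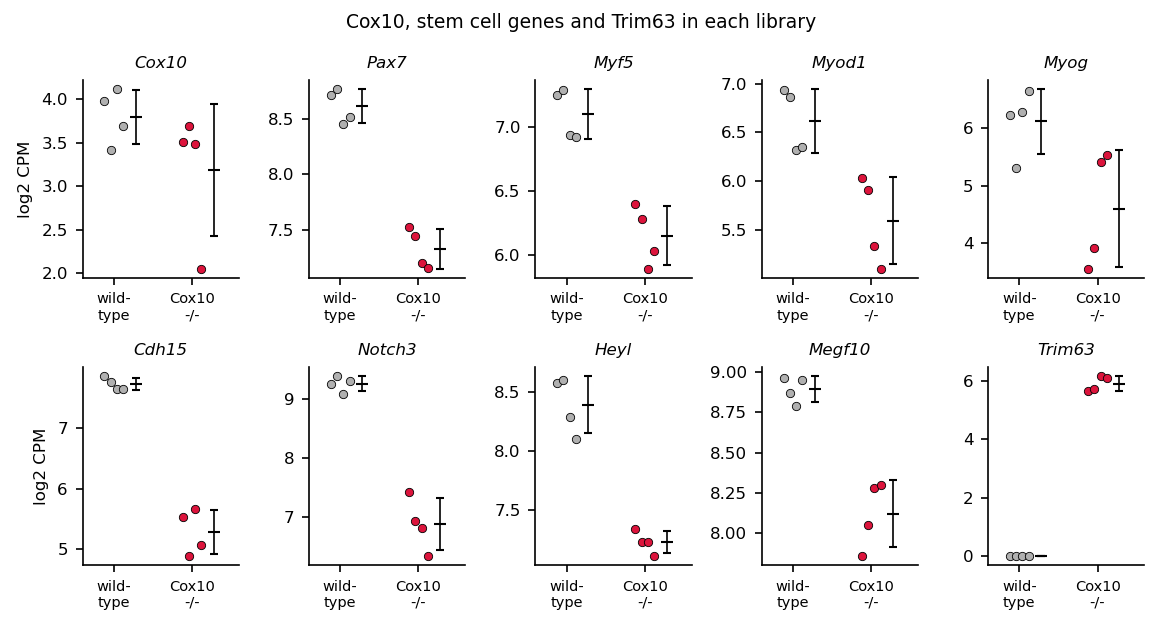
Each panel shows 1 gene, with the 4 wild-type (grey) and 4 Cox10-/- (red) libraries as points in log2 CPM and the mean with SD beside them. Pax7 averaged 8.62 in wild-type and 7.33 in Cox10-/-, and Trim63 was at 0 in wild-type and 5.91 in Cox10-/-.

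Of the lists of nuclear-encoded respiratory chain subunits, those of complex I and ATP synthase passed the list test, and those of complex II and III and of complex IV did not; a difference between the lists was not tested. Of 36 complex I subunits 35 lay below 0, and 5 fell (9 adjusted over the list alone; camera adjusted p = 7.4e-05; adjusted p = 0.351 with an estimated correlation): Ndufs8 by 0.72 ± 0.17, Ndufc1 by 0.73 ± 0.22, Ndufs6, Ndufa9 and Ndufa12. Of 16 ATP synthase subunits 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00157; adjusted p = 0.351 with an estimated correlation), among them Atp5o by 0.64 ± 0.16 and Atp5g2 by 0.59 ± 0.15. Of 19 complex IV assembly and haem A factors 5 fell (6 adjusted over the list alone; camera adjusted p = 0.0398; adjusted p = 0.66 with an estimated correlation): Cox14 by 1.10 ± 0.27, Cmc2 by 1.09 ± 0.27, Coa3, Cox15, which converts haem O to haem A, by 0.58 ± 0.14, and Lrpprc. That list lost its call without wild-type replicate 4 (adjusted p = 0.0828), Cox10-/- replicate 1 (0.0596) and Cox10-/- replicate 2 (0.0518). Of 74 mitochondrial ribosomal proteins 9 fell, among them Mrps16 by 0.93 ± 0.24, and Mrpl41 rose by 1.03 ± 0.18 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00272; adjusted p = 0.663 with an estimated correlation). Of 14 complex II and III subunits 1 fell, Cyc1 by 0.56 ± 0.16 (3 adjusted over the list alone; camera adjusted p = 0.0594), and 11 lay below 0. That list passed without wild-type replicate 3 (0.0424), Cox10-/- replicate 4 (0.0221) and the 2 shallowest libraries (0.0254), with a term for depth (0.0418) or for replicates 1 and 2 against 3 and 4 (0.0497), and in fry's directional test (0.00414). Of 15 complex IV subunits none fell at the adjusted threshold and Cox4i2 rose by 1.21 ± 0.33 (none and 1 adjusted over the list alone; camera adjusted p = 0.099), and 13 lay below 0. That list passed without Cox10-/- replicate 4 (0.0386), with a term for depth (0.0444) and in fry's directional test (0.00239). Cox4i2 lay near the floor of 0, at a mean of 0.34 log2 CPM in wild-type and 1.545 in Cox10-/-. Without 1 library, single calls were often lost: Ndufa9 and Ndufa12 lost theirs in 7 of the 8 fits without 1 library, Ndufc1 and Coa3 in 6, Ndufs6, Lrpprc, Cyc1 and Cox4i2 in 5, Mrps16 in 4, Atp5g2 in 3 and Cmc2 in 2. Cox15 and Atp5o lost theirs in 1, without wild-type replicate 4 (0.0551) and wild-type replicate 1 (0.0711). The largest adjusted p among these was 0.131, for Ndufa12 without Cox10-/- replicate 3, and Ndufa12 and Coa3 were named after their values were seen. With 2 means per genotype no single call named in this paragraph held (adjusted p from 0.0556 for Mrpl41 to 0.273 for Ndufa12), and complex IV assembly lost its list call (0.0554). The 15 mitochondrially encoded transcripts had no call (camera adjusted p = 0.642), but the list passed without wild-type replicate 3 (0.0224) and Cox10-/- replicate 4 (0.0465), with a median of -0.80 in replicates 1 and 2 and of 0.59 in replicates 3 and 4.

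Of the lists in this paragraph, cholesterol synthesis and hypoxia-inducible factor targets passed the list test. Cholesterol synthesis and uptake had 11 falls and no rise among 24 genes (13 and none adjusted over the list alone; camera adjusted p = 7.4e-05; adjusted p = 0.575 with an estimated correlation). Among them, Nsdhl fell by 1.5 ± 0.32, the cholesterol carrier Stard4 by 1.10 ± 0.22, and Srebf2, the regulator of the pathway, by 0.70 ± 0.12. Of 22 hypoxia-inducible factor targets 7 rose and 2 fell, as when adjusted over the list alone (camera adjusted p = 0.0088; adjusted p = 0.289 with an estimated correlation). The mitophagy receptor Bnip3 rose by 1.59 ± 0.19, Pdk1, which inhibits pyruvate dehydrogenase, by 0.76 ± 0.10 and Mxi1 by 0.54 ± 0.10, while the collagen hydroxylase P4ha2 fell by 0.80 ± 0.13. Glycolysis did not pass as a list (camera adjusted p = 0.642): Eno1 (-0.86), Hk1 (-0.61), Pkm (-0.53) and Pgk1 (-0.50) fell and Hk2 rose by 0.79 ± 0.17. Targets of ATF4, the transcription factor of the integrated stress response, went both ways, 7 up and 6 down of 40 (9 and 7 adjusted over the list alone; camera adjusted p = 0.922). Cth and Cbs, enzymes of cysteine synthesis, rose by 1.86 ± 0.31 and 1.75 ± 0.26, and Pycr1 and Psat1, enzymes of proline and serine synthesis, fell by 2.41 ± 0.41 and 1.12 ± 0.21. Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 0.83 ± 0.15 in a list of 25 that did not pass (6 up and 2 down, 6 and 3 adjusted over the list alone; camera adjusted p = 0.443). The call of Pgk1, named after its values were seen, was lost in 4 of the 8 fits without 1 library (adjusted p up to 0.0653, without wild-type replicate 4). Those of Mxi1, Pkm and Pgk1 were lost with 2 means per genotype.

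Mitotic transcripts were higher. All 30 measured lay above 0 with a median of 1.05, and 12 rose (27 adjusted over the list alone; camera adjusted p = 9.0e-10; adjusted p = 0.597 with an estimated correlation; fry directional adjusted p = 0.119). Aurkb rose by 1.45 ± 0.40, Cdc20 by 1.20 ± 0.33, Nusap1 by 1.18 ± 0.31 and Anln by 0.97 ± 0.27, and these single calls were lost in 6, 5, 3 and 6 of the 8 fits without 1 library, with adjusted p up to 0.0899, all at their largest without Cox10-/- replicate 3. In 30 replication genes Mcm2 (-1.53), Tyms (-1.25) and Pola1 (-0.86) fell and Mcm7 (0.46) and Mcm10 (1.30) rose, as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.642). Mcm7 lost its call without wild-type replicate 1 (0.0594) and Mcm10, named after its values were seen, in 5 fits (up to 0.101 without Cox10-/- replicate 3). Ribosome biogenesis had 8 falls and no rise of 37, as when adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.66 with an estimated correlation; fry directional adjusted p = 0.0544), with the pyrimidine synthesis enzyme Cad at -1.39 ± 0.18 and Bop1 at -0.85 ± 0.17. Of 79 cytosolic ribosomal proteins 4 fell (none adjusted over the list alone; camera adjusted p = 0.00534; adjusted p = 0.858 with an estimated correlation): Rpl29 (-0.65), Rpl13a (-0.50), Rps10 (-0.45) and Rpl22 (-0.38). The ribosomal protein list had a median of -0.54 in replicates 1 and 2 and of 0.17 in replicates 3 and 4, and lost its call without wild-type replicate 2 (0.469), Cox10-/- replicate 1 (0.165) and Cox10-/- replicate 2 (0.0567), after median centring (0.0579) and after the length and GC correction (0.0839). The single calls of Rps10, Rpl22, Rpl29 and Rpl13a were lost in 6, 5, 3 and 1 of the 8 fits. All 4, and those of Aurkb, Nusap1, Anln, Tyms, Mcm7, Mcm10 and Bop1, were lost with 2 means per genotype.

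Lysosomal and autophagy transcripts had 5 rises and no fall of 27, as when adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.289 with an estimated correlation): the protease Ctsl by 0.93 ± 0.17, Wipi1 (named after its values were seen) by 0.76 ± 0.17, the autophagosome protein Map1lc3b by 0.59 ± 0.09, Gabarapl1 by 0.57 ± 0.12 and Ulk1 by 0.47 ± 0.08. The lysosomal list had an adjusted p of 0.0622 after a correction for transcript length and GC content. Immediate-early genes had 4 rises and no fall of 30, as when adjusted over the list alone (camera adjusted p = 9.0e-04; adjusted p = 0.692 with an estimated correlation): Nr4a2 by 0.75 ± 0.14, Dusp5 by 0.48 ± 0.14, Klf2 by 0.39 ± 0.10 and Klf4 by 0.37 ± 0.08. The median of that list was -0.12 in replicates 1 and 2 and 0.48 in replicates 3 and 4, and fry's directional test gave an adjusted p of 0.282. Dusp5 and Klf2 lost their calls in 5 and 3 of the 8 fits without 1 library (adjusted p up to 0.084 and 0.068). With 2 means per genotype Wipi1, Gabarapl1, Ulk1, Dusp5, Klf2 and Klf4 lost theirs. The p53 targets Trp53inp1 (1.35 ± 0.15) and the cell cycle inhibitor Cdkn1a (0.72 ± 0.10), rose in a list of 30 with 5 rises and 3 falls, as when adjusted over the list alone, that did not pass (camera adjusted p = 0.114). Of 23 apoptosis regulators 4 rose, among them Hrk by 2.24 ± 0.31 and Bcl2l1 by 0.91 ± 0.12, and 2 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.649).

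Of the lists of markers of other cells and of fibre transcripts, only the endothelial one passed the list test. Some of these markers were abundant in wild-type libraries already. Pdgfra averaged 8.39 log2 CPM there, Pdgfrb 7.30 and Myh11 7.23, against 8.62 for Pax7. Others were low, with Flt1 at 3.17, Esam at 1.71 and Ly6a at 1.245. These examples were chosen after their values were seen, and which cells the transcripts came from was not tested. Of 18 endothelial markers 6 rose and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 7.4e-05; adjusted p = 0.351 with an estimated correlation), among them Ly6c1 by 1.89 ± 0.30, the vascular growth factor receptor Flt1 by 1.71 ± 0.31, Esam by 1.63 ± 0.33 and Cdh5 by 0.47 ± 0.12. Fibroblast and fibro-adipogenic markers (3 up and 1 down of 18, 4 and 1 adjusted over the list alone; camera adjusted p = 0.484) did not pass, with Ly6a at 1.84 ± 0.47, Pdgfra at 0.84 ± 0.19, Cxcl14 at 0.74 and Dpt at -0.54. Pericyte and smooth muscle markers (2 up and 3 down of 13, 3 and 4 adjusted over the list alone; camera adjusted p = 0.649) held rises of Myh11 by 1.28 ± 0.22 and Pdgfrb by 0.91 ± 0.14, and falls of Notch3, Cspg4 by 0.60 and Acta2 by 0.36. Fibre transcripts (3 up and 2 down of 18, the same adjusted over the list alone; camera adjusted p = 0.0973, and 0.0448 and 0.00418 without wild-type replicate 4 and Cox10-/- replicate 2, 0.0471 with a term for replicates 1 and 2 against 3 and 4 and 0.0337 with a term for the mitochondrial split) held rises of Ckm (1.54), Tcap (1.44) and Tnnt3 (1.31) and falls of Ryr1 (-2.04) and Actn3 (-1.13). The tendon regulator Scx fell by 1.92 ± 0.27 and Tnc by 0.73 (2 of 10 tenocyte markers), Gfra3 by 2.40 ± 0.39 (1 of 14 Schwann cell markers), and Hbb-bs and Hba-a1 rose by 1.85 and 1.46 (2 of 7 erythroid transcripts, 4 adjusted over the list alone; camera adjusted p = 0.125, and 0.0496 without wild-type replicate 1). None of 6 measured leukocyte markers changed. Xist was 0.08 ± 0.10 (adjusted p = 0.647). Without 1 library, calls were lost for Acta2 in 7 fits, Cdh5 in 4, Ckm, Cxcl14 and Hba-a1 in 2, and in 1 each for Ly6a (0.0692), Tcap (0.0654) and Cspg4 (0.0606), without Cox10-/- replicate 3, and Dpt (0.0503), without Cox10-/- replicate 2. Acta2 and Ckm were named after their values were seen. The calls of Cdh5, Ly6a, Pdgfra, Cxcl14, Dpt, Cspg4, Acta2, Ckm, Tcap, Tnc and Hba-a1 were lost with 2 means per genotype.

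**Figure D3:**
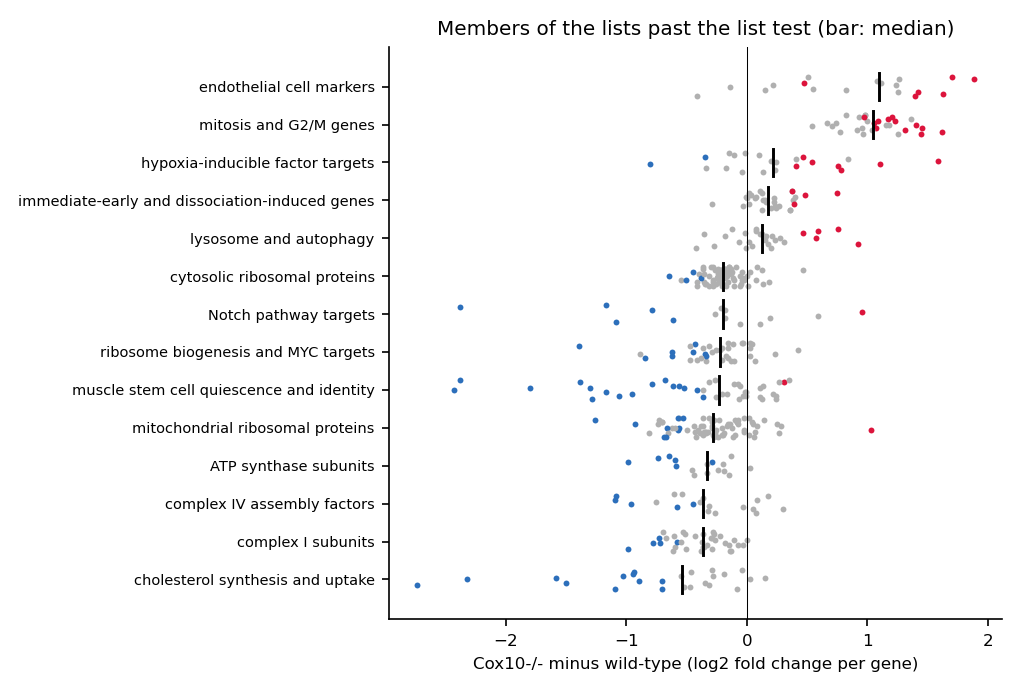
Each point is a gene of 1 of the 14 lists past the list test, at its log2 fold change of Cox10-/- against wild-type; coloured points passed the gene test, and the bar is the median of the list. Medians ran from -0.54 for cholesterol synthesis to 1.10 for endothelial markers.

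Of 43 lists tested with camera, 14 passed, 5 higher and 9 lower, and none passed with an estimated correlation, where the smallest adjusted p was 0.229. The other 29 lists did not pass, although 10 of them did in some fit without 1 library. Among the 29, the median, mean or test differed in sign for mitochondrial biogenesis, NRF2 targets, heat shock genes, apoptosis regulators, tenocyte markers and nuclear-retained transcripts. Fry's directional test, which asks only whether a list moved one way, passed 14 lists, 10 of them among those 14.

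**Figure D4:**
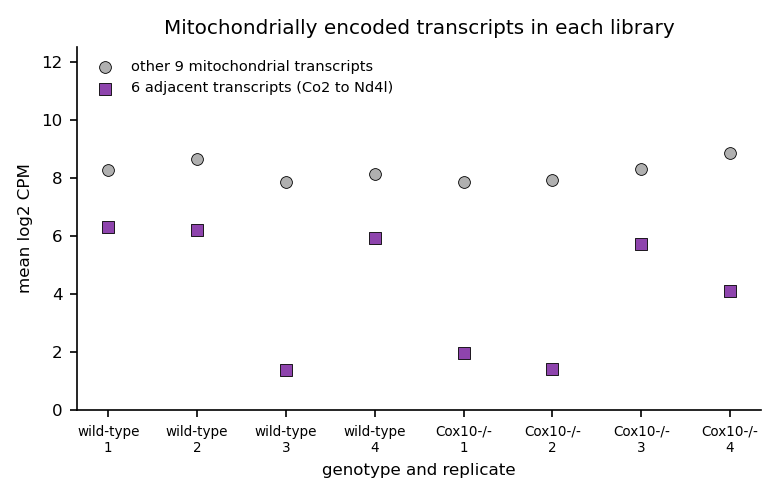
Mean log2 CPM of 6 adjacent mitochondrially encoded transcripts (squares) and of the other 9 (circles) in each library. The 6 averaged 1.37, 1.97 and 1.42 in wild-type replicate 3 and Cox10-/- replicates 1 and 2, 4.10 in Cox10-/- replicate 4 and 5.73 to 6.32 in the other 4 libraries.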

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

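Of the tests in this part, that of the share of stem cells was chosen after the result was seen, and the others were set before the values they measure were seen. In 298 groups of 4 libraries (each gene that this text names and the depth, per genotype), 25 had 1 library whose gap to its nearest neighbour exceeded 0.829 of the range, where chance gives about 5%. Values are log2 CPM.

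Wild-type replicate 3 stood low for 6 mitochondrially encoded transcripts: mt-Nd3 and mt-Atp8 at 0, mt-Nd4l at 0.59, mt-Co2 at 2.69, mt-Atp6 at 2.69 and mt-Co3 at 2.24, against at least 4.37 in the other wild-type libraries. Cox10 in Cox10-/- replicate 4 was 2.05, against 3.49 to 3.69. Wild-type replicate 2 stood low for Iqsec3 (7.01), Nwd1 (4.54), Dll1 (5.83) and Atp5g2 (4.78), and high for Ctsl (7.51). In wild-type replicate 4, Aspg (1.31) and Ly6c1 (0.58) were above 0 while the other 3 were at 0, and Eno1 (6.90) was high. Wild-type replicate 1 was low for Hrk (0.98) and high for Mirg (6.62). Among Cox10-/- libraries, replicate 3 was high for Arhgef37 (5.06), Flt1 (5.17) and Cry2 (7.37), replicate 2 was high for Ephb1 (2.52) and low for Anln (5.27), replicate 1 was low for Insr (8.66), and replicate 4 was low for Psat1 (4.19) and high for Hbb-bs (3.82).

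The 6 transcripts lie next to each other on the mitochondrial genome and were lower by 3.59 to 4.52 in wild-type replicate 3 and Cox10-/- replicates 1 and 2 than in the other 5 libraries, of which Cox10-/- replicate 4 was intermediate. A median of 99.2% of their 50-mers also occurred in another annotated gene (0% for mt-Atp8), against 1.04% in the other 9 (62.2% for mt-Nd4 and 51.1% for mt-Co1), so reads shared with nuclear copies are a candidate explanation. A rule for such reads that differed between libraries would also lower nuclear genes with shared sequence, but 106 of these differed by a median of -0.082, far from the -0.5 set beforehand, although below all 10000 matched random lists (0.20, 0.15 to 0.27). A sequence difference in mitochondrial DNA between animals stays open and was not tested, and genotype does not divide the libraries this way.

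Stem cell genes were lower in Cox10-/-. A lower share of stem cells, with an even rise of all other cells, would lower restricted genes alike and raise other cells' markers alike. The 16 restricted genes, chosen after the result was seen, differed among themselves by Cochran's Q of 424 on 15 degrees of freedom (Cdh15 -2.43 to Msc 0.27). Medians were 1.10 (95% interval over list members 0.49 to 1.33) for endothelial, 0.11 (-0.32 to 0.39) for fibroblast and 0.02 (-0.46 to 0.15) for tenocyte markers. These values go against an even replacement as the whole cause. An uneven one, or restricted genes that other cells also express, would give unequal changes too, so the test cannot exclude a lower share as the whole cause. All 8 medians lay above 0, with erythroid 0.92, fibre 0.62, leukocyte 0.59, pericyte 0.35 and Schwann 0.27 markers, whose intervals overlapped the endothelial one. A lower share of stem cells therefore stays open as a part or the whole of the fall. With depth as a second term the median of the 16 members that fell was -0.98, against -1.0 without, and depth did not differ detectably (exact permutation p = 0.686). The genotype stays open, as does Cre activity, since the labels do not say whether wild-type animals carried the driver.

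Respiratory chain transcripts are short, at a median of 1046 bases against 3018. The median of 81 nuclear-encoded genes was -0.33, below all 10000 random lists matched on length, GC content and expression (-0.11, -0.20 to -0.03). After correction for length and GC content it was -0.27 ± 0.04, a standard error over the list members and not between libraries. Both comparisons take the genes as independent, and with an estimated correlation the complex I and ATP synthase lists had a camera adjusted p of 0.351. The correction for this bias thus left a median below 0, but its error between libraries was not measured. Whether the remainder reflects the loss of Cox10 or another difference between the groups stays open.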

How the results depend on the processing

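Alternatives with a second term, without the 2 shallowest libraries, with means of replicates, with voom and with a length and GC correction were chosen after seeing the data. No changed gene had the opposite direction in any alternative that tested it. The count of changed genes was 1840 to 2907 without 1 library, lowest without Cox10-/- replicate 3 and highest without wild-type replicate 2, 858 with means of replicates 1 and 2 and of 3 and 4 as 2 samples per genotype, and 2210 to 4256 in the other alternatives. With these means, which leave fewer degrees of freedom, changes of a log2 fold of 1 or more numbered 567, and 75 of 160 calls of the naming rule and 13 of 14 list calls were kept. Whether the loss comes from fewer degrees of freedom or from libraries that are not independent was not tested. The kept list calls cannot decide this, since camera with a preset correlation rests on the spread over genes. Changes of a log2 fold of 1 or more numbered 554 with the stricter filter, which tested fewer genes, and 392 with a pseudocount of 5, which shrinks low values by construction. With the replicate block 3201 genes changed (1573 higher, 1628 lower), and 13 of the 14 lists kept their call; complex IV assembly did not (0.0571), and fibre transcripts gained one (0.0326). Ndufs6 (0.0552), Ndufa9 (0.0512) and Ndufc1 (0.0594), and 1 other gene of the naming rule, lost their calls with the block, and 8 gained one. The libraries were not treated as pairs: over all tested genes same-number correlations were 0.0453, 0.137, 0.109 and 0.130, 1 of them under 0.1, and 4 of 8 libraries correlated best with their own number. Over the 11682 genes with a mean log2 CPM of 3 or more all 4 exceeded 0.1 (0.106, 0.223, 0.201 and 0.177), so this decision depends on the genes used. Cox10 ranged from -0.79 to -0.24, with adjusted p from 0.0778 to 0.507.

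Of 160 genes that the naming rule selects and that passed the test, 72 kept their call and direction in all alternatives run. List calls numbered 0 with an estimated correlation and 34 with fry's mixed test, which asks another question; each of the 14 lists lost its call in some alternative. No called list or gene reversed. Uncalled results reversed, at an adjusted p of 0.314 to 0.989 in the alternatives concerned, and the cause was not tested. Heat shock genes did so with the replicate block (0.860), quantile normalization (0.730), a term for replicates 1 and 2 against 3 and 4 (0.783), the depth term (0.529) and the length and GC correction with replicate block (0.926), and Xist with quantile normalization (-0.019). With the mitochondrial split term, mitochondrially encoded transcripts (0.686), ATF4 targets (0.832) and tenocyte markers (0.631) reversed. Without the 2 shallowest libraries, ATF4 targets (0.900), DNA replication genes (0.900) and fibroblast markers (0.752) did. Mitochondrially encoded transcripts reversed with the length and GC correction with replicate block (0.966). In fry's directional test, NRF2 targets (0.989), DNA replication genes (0.980) and pericyte markers (0.873) did. Without 1 library, mitochondrially encoded, ATF4, heat shock and tenocyte lists reversed in 3 of the 8 fits each, and DNA replication, nuclear-retained, extracellular matrix and fibroblast lists in 1 each. Their adjusted p without 1 library ranged from 0.0224 to 0.784 for mitochondrially encoded transcripts, 0.808 to 0.977 for ATF4 targets, 0.151 to 0.920 for DNA replication, 0.114 to 0.860 for heat shock, 0.103 to 0.977 for tenocyte, 0.375 to 0.990 for nuclear-retained, 0.00221 to 0.841 for extracellular matrix and 0.119 to 0.860 for fibroblast lists. On data simulated with the moderated variances of the fit, the measured depths (1693349 to 4650051 reads) and 200 changed genes, 10.4% of log2 changes of 0.5 were called. Fewer genes changed there than were called in the data, which makes the adjusted threshold stricter, so this share may be an understatement. What limits it was not tested.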

Other observations

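Gene groups in this paragraph were chosen after their values were seen. Of 18 clock genes 4 rose and 4 fell. Among them, Npas2 rose by 1.74 ± 0.10 (log2, SE, n = 4 per genotype), Cry2 by 0.75 and Arntl by 0.73 ± 0.13, and the clock output gene Dbp fell by 1.44 ± 0.14, Per3 by 1.01 ± 0.14, Bhlhe41 by 0.96 and Per2 by 0.53. The call of Per2 was lost in 5 of the 8 fits without 1 library (adjusted p up to 0.0583, without wild-type replicate 3), and those of Per2, Ckm and Tcap with means of replicates 1 and 2 and of 3 and 4 as 2 samples per genotype. Of 27 targets of the glucocorticoid receptor and FoxO factors 14 rose and none fell, among them Trim63, the tyrosine catabolism enzyme Tat by 3.19 ± 0.31, Klf15 by 1.18 ± 0.16, the insulin receptor Insr by 1.07 ± 0.08 and the ubiquitin ligase Fbxo32 by 1.02 ± 0.16. In the imprinted Dlk1-Dio3 domain, of which 3 of 6 members were measured, Mirg fell by 1.90 ± 0.16 and B830012L14Rik by 1.71, and Dio3, which inactivates thyroid hormone, rose by 2.25 ± 0.33. Of 12 abundant fibre transcripts 3 rose (Ckm, Tcap and Tnnt3, which also rose in the fixed fibre list) and none fell. Ryr1 and Actn3, which fell in the fixed list, are not among these 12, so the lack of falls depends on the choice of members. Hours of collection are not in the labels.

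Some lists differed between replicates 1 and 2 and replicates 3 and 4 in the same direction in both genotypes, which was not tested per list. The median difference was 0.89 in wild-type and 1.05 in Cox10-/- for Schwann cell markers, -0.91 and -0.89 for fibre transcripts and -0.84 and -0.94 for mitotic genes. Others went opposite ways, at 0.49 and -0.35 for heat shock genes, 0.41 and -0.32 for cytosolic ribosomal proteins, 0.36 and -0.22 for immediate-early genes and 0.59 and -0.81 for mitochondrially encoded transcripts. With this division as a second term 3838 genes changed between genotypes, and all 2863 were kept. Of 35 splits of the 8 libraries into 4 and 4, 1 (the genotypes) gave as many as 2863 calls. The highest other gave 6, which was the division by replicate number. With the 8 libraries taken as independent, this is less than the 1 in 20 set beforehand. If replicates 1 and 2, and 3 and 4, are not independent, too few splits exist to reach 1 in 20. The test then cannot exclude chance.

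DNA that stays linked to the targeted alleles might have changed genes near Cox10 and Pax7. Of their 200 tested neighbours 14% changed (9 of 100 near Cox10 and 19 of 100 near Pax7), against 16.1% of all genes (Fisher's exact test, two-sided, p = 0.498). This argues against a broad excess over these neighbours. A change in a few of them would not be seen in the pooled share, so such an effect is not excluded.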
